A study of Mus musculus with 20 samples.

How the data were processed

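Total RNA from the left and right brain hemispheres of 10 C57/Bl6 mice was measured on 20 biotin-labelled arrays, 5 for each of 4 groups. All animals had LPS-sensitised hypoxia-ischemia with injury of the left hemisphere, and 5 of them had received the peptide IDR1018. Per the submitters' processing notes, the authors ran RMA in the affy package 1.38.1, so the deposited values are log2 probe set summaries after background correction and quantile normalisation. Background settings and the chip definition were not stated. The values were used as deposited. Array medians lay between 8.20 and 8.23, and Pearson correlations between arrays, taken across probe sets, between 0.994 and 0.998. The number of arrays limits the precision of all results.

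The deposited table held 34760 probe sets. Of these, 6568 were treated as control probe sets, because their identifiers precede the first annotated one, and were left out, which left 28192 for testing. None of the 6568 passed the test in any of the 5 comparisons by limma. In the platform annotation 21640 probe sets carried exactly 1 gene symbol, 1321 carried several and 5231 were not listed. Names were checked against a RefSeq table of assembly GRCm38.p6, in which the Entrez identifiers of 21553 probe sets matched. Its coordinates were used to choose the microRNA genes between Dlk1 and Dio3. For gene-level work each of 19937 genes was represented by its probe set with the highest mean over all 20 arrays.

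The comparisons were left against right without peptide, left against right with peptide, peptide against no peptide in each hemisphere, and the difference of the left-right differences. Each was fitted with limma 3.58.1 in R 4.3.3 on the arrays of the groups compared, with Benjamini-Hochberg adjustment over all 28192 probe sets and a threshold of 0.05. Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 43 lists per comparison. Camera with an estimated correlation and fry stand beside it. The lists named 630 members, of which 576 were measured. Comparisons, lists, the rule for naming genes and most alternatives were fixed before the data were examined.

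An injury score per animal was the mean left minus right difference over the 200 genes with the strongest rise, or the strongest fall, in the left hemisphere over both treatments. Scores and list means per animal were compared by two-sided exact permutation tests. With 5 animals against 5 there are 252 arrangements and the smallest possible p is 0.00794. The relation of peptide effect to injury effect across genes was computed with the shared arrays divided between the effects, and also on simulated unchanged groups.

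The text names up to 10 genes with the largest increase and 10 with the largest decrease among those past the threshold in a comparison. Where fewer than 3 genes passed, the 5 higher and the 5 lower genes with the smallest p take their place. It also names up to 4 members of the 12 lists with the smallest p, and a fixed panel of 12 genes whatever their values; 1 panel gene, C3, was not analysed here. Genes named outside this rule are marked as chosen after their values were seen.

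Left and right arrays of a replicate number share a specimen number. As a check, Xist and Y-linked transcripts were compared between them, with 0 mismatches in 10 animals, 3 male and 2 female without peptide and 2 male and 3 female with it. Apart from sex, the arrays of an animal resembled each other little: the consensus correlation of the 2 arrays of an animal after the group means were removed was 0.0690. The main left-right and interaction fits did not pair these arrays, so their SE hold the variation between animals. With the replicate block, which pairs them, the counts between hemispheres were 4778 without peptide and 3383 with it. Single genes can depart from the consensus: Lcn2 passed without peptide only with this block. Replicate numbers do not pair animals with and without peptide. Array numbers 1 to 10 were all left hemispheres and 11 to 20 all right hemispheres, so array order and hemisphere cannot be told apart.

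The steps were tested on simulated data with the variances of these arrays, a single draw per setting with each probe set drawn independently. In the peptide comparison of the injured hemisphere, limma found 48.0% of probe sets changed 1.2-fold and 88.0% of those changed 1.5-fold among 28192; in the uninjured hemisphere it found 56.0% and 94.0%, and for the interaction 28.0% and 92.0%. In the comparison of hemispheres without peptide the shares were 60.0% and 96.0%, and with peptide 60.0% and 98.0%. When a share of 0.5 of the injury effect was removed in simulated animals, the injury score chosen from 19937 genes recovered a share of 0.509. A gene list shifted by 0.15 log2 units was found by camera and fry in all 5 comparisons, with 1 false call by camera in the uninjured hemisphere. With an estimated correlation it was found in 4 comparisons and missed in that of peptide in the injured hemisphere. In the real arrays members of a list varied together, with a median estimated correlation over the lists of 0.175 to 0.286. How the list tests behave under such correlation was not tested by this simulation. Alternatives were another normalisation, centring, removal of dim probe sets, other variance models, array weights, a fold threshold, a replicate block, sex or the level of the control probe sets as a covariate, and omission of each array and of each animal. Figures were drawn with matplotlib 3.10.9.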

Results

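The 20 arrays covered both hemispheres of 10 mouse brains after LPS-sensitised hypoxia-ischemia, a model in which exposure to bacterial lipopolysaccharide precedes a hypoxic-ischemic insult that injures the left hemisphere. Brains came from adult mice per the labels, and neither dose nor time of collection is stated. There were 5 arrays in each of 4 groups: injured left and uninjured right hemisphere, without or with IDR1018, a synthetic peptide that modulates innate immune responses. No group was free of LPS and hypoxia-ischemia, so the right hemisphere of the same animals is the reference for injury. The median SD between replicates over probe sets was 0.082 log2 units in the left hemispheres without peptide and 0.078 with it, and 0.074 and 0.077 in the right hemispheres.

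The comparison of injured left with uninjured right hemispheres without peptide asks what the injury did to the tissue. Chemokines led the increases. Ccl3, which attracts monocytes and other leukocytes, was 17.0-fold higher in the injured hemisphere (log2 fold change 4.09 ± 0.19, SE, n = 5 per group, adjusted p = 1.3e-06). The monocyte attractant Ccl2 rose by 2.54 ± 0.19, the stress-induced transcription factor Atf3 by 2.61 ± 0.25, the membrane protein gene Emp1 by 2.07 ± 0.10 and the heat shock gene Hspa1a by 1.94 ± 0.17, each higher in the left hemisphere of 5 of 5 animals. Other large increases were those of Ccl9 (2.04 ± 0.12), Lilr4b (1.95 ± 0.12), Gpr84 (1.87 ± 0.10), Il1a (1.86 ± 0.27) and the interferon-inducible chemokine Cxcl10 (1.84 ± 0.13). The largest decreases were smaller. Mir421 fell by 0.89 ± 0.15, Mir379 by 0.81 ± 0.16, Slc6a13, a GABA and taurine transporter of the meninges, by 0.80 ± 0.14, and Mir128-1 by 0.80 ± 0.10. In the fibroblast and meninges list, which holds Slc6a13, 3 of 12 measured genes fell (3 adjusted over the list alone) and the list did not pass camera.

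Innate immune genes were among the increases. In the cytokine and chemokine list 16 of 24 measured genes rose (19 adjusted over the list alone), with a median log2 fold change of 0.70. On the fixed panel Il1b, a mediator of fever and inflammation, rose by 1.15 ± 0.18 from values below the median of the control probe sets in 5 of 5 right arrays. Tnf rose by 0.83 ± 0.15, while Il10 did not pass the test (-0.05 ± 0.05). Il10 lay below the median of the control probe sets in all 20 arrays of the 4 groups, so its lack of change tells little. The list passed camera (adjusted p = 7.2e-14; adjusted p = 0.16 with an estimated correlation). Among TLR and NF-kB signalling genes 14 of 18 rose (16 adjusted over the list alone), among them the LPS co-receptor Cd14 (1.80 ± 0.15) and the receptor Tlr2 (0.64 ± 0.07); adjusted p = 8.2e-11 by camera and adjusted p = 0.13 with an estimated correlation. Interferon response genes rose in 11 of 20 cases (16 adjusted over the list alone), with Ifit3 at 1.28 ± 0.13 and Rsad2, an antiviral enzyme, at 1.03 ± 0.14; adjusted p = 1.1e-08 and adjusted p = 0.25 with an estimated correlation.

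Microglial genes went both ways. Of the phagocytic and activated microglia list 14 of 19 rose (15 adjusted over the list alone), including the scavenger receptor Msr1 (1.15 ± 0.14), the chemokine Ccl6 (1.43 ± 0.08) and the panel gene Cd68, a lysosomal marker (0.36 ± 0.05). Of the homeostatic microglia list 9 of 13 fell and 1 rose, the same numbers as adjusted over the list alone, with a median of -0.24. Camera gave adjusted p = 1.1e-12 and adjusted p = 8.9e-05 for these lists; with an estimated correlation the values were adjusted p = 0.067 and adjusted p = 0.28. Reactive astrocyte genes rose in 16 of 20 cases (18 adjusted over the list alone), with a median of 0.60. Among them were Hspb1, a small heat shock protein (1.47 ± 0.10), the cytokine receptor Osmr (1.15 ± 0.07) and Gfap, the astrocyte filament protein (0.32 ± 0.05); adjusted p = 3.2e-16 and adjusted p = 0.060 with an estimated correlation. Lcn2, which neutrophils also express, was 0.63 ± 0.26 higher without passing the test (adjusted p = 0.11; it passed with the replicate block, adjusted p = 0.00068).

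Stress and cell death genes rose as well. Of the heat shock and unfolded protein response list 12 of 15 rose (12 adjusted over the list alone), among them Atf4, a transcription factor of the integrated stress response (0.65 ± 0.05). Of the p53 and apoptosis list 9 of 13 rose (12 adjusted over the list alone), including the pro-apoptotic Bcl2l11 (0.69 ± 0.09) and the death receptor Fas (0.61 ± 0.15; adjusted p = 0.017, and 0.0565 or 0.0589 without both arrays of no-peptide replicate 1 or 5). This was the 1 list in this comparison past the threshold with an estimated correlation (adjusted p = 0.036); the heat shock list had adjusted p = 0.060. Immediate early genes rose in 11 of 20 cases (14 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation), among them Fos (1.68 ± 0.30) and Fosb (1.16 ± 0.23). In the NRF2 and metallothionein list 7 of 14 rose (7 adjusted over the list alone; adjusted p = 0.060 with an estimated correlation), led by the heme-degrading enzyme Hmox1 (1.56 ± 0.11). Extracellular matrix genes rose in 10 of 19 cases (12 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), with the protease Plau at 1.25 ± 0.14 and Timp1, a protease inhibitor, at 0.87 ± 0.16.

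Genes of striatal projection neurons and of synapses fell, whereas most members of the other neuronal lists did not pass. Of the striatal projection neuron list 9 of 10 fell (9 adjusted over the list alone), with the neuropeptide precursor Penk lower by 0.49 ± 0.10, the dopamine signalling protein Ppp1r1b lower by 0.48 ± 0.08 and the dopamine receptor Drd2 lower by 0.45 ± 0.09. Of the synaptic receptor and scaffold list 8 of 12 fell (11 lower and 1 higher adjusted over the list alone), including the adhesion protein Nlgn1 (-0.38 ± 0.05) and the glutamate receptor subunit Gria3 (-0.34 ± 0.05). Both lists had adjusted p = 2.5e-06 by camera and adjusted p = 0.25 with an estimated correlation. Pan-neuronal genes fell in 3 of 14 cases (5 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), and Snap25, a presynaptic protein, was at -0.09 ± 0.03 (adjusted p = 0.052; below the threshold in 7 alternatives, with adjusted p from 0.00344 to 0.0415). Of excitatory neuron genes 2 of 13 fell and 1 rose (5 and 1 adjusted over the list alone), of inhibitory neuron genes 2 of 13 fell (2 over the list alone), and of immature neuron genes 1 of 11 fell and 1 rose (3 and 2 over the list alone); these 3 lists did not pass camera (adjusted p = 0.15, 0.076 and 0.64). The myelin gene Mbp differed by 0.01 ± 0.07. Lists for choroid plexus, cerebellum, cell cycle, lymphocytes and blood monocytes did not pass the test.

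In all, 5088 probe sets differed between hemispheres without peptide, 2597 higher and 2491 lower in the injured left; at 1.5-fold or more these were 188 and 38. The balance of directions depends on the scaling: after median centring 2162 were higher and 3007 lower. Leaving out both arrays of an animal lowered the count to 2698 for no-peptide replicate 5, 2788 for replicate 4 and 3325 for replicate 2. With the level of the control probe sets as a covariate it was 2927, of which 2620 were shared. Of the 43 lists 21 passed camera and 26 passed fry. Among 100 splits of these 10 arrays 29 put as many past camera, and 11 of 99 did after the group means were removed. The lists are therefore described by their member counts, to be read against all 19937 genes, of which 2085 were higher and 2005 lower. Members of a list vary together, so a member count is no test of a list either.

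**Figure D1:**
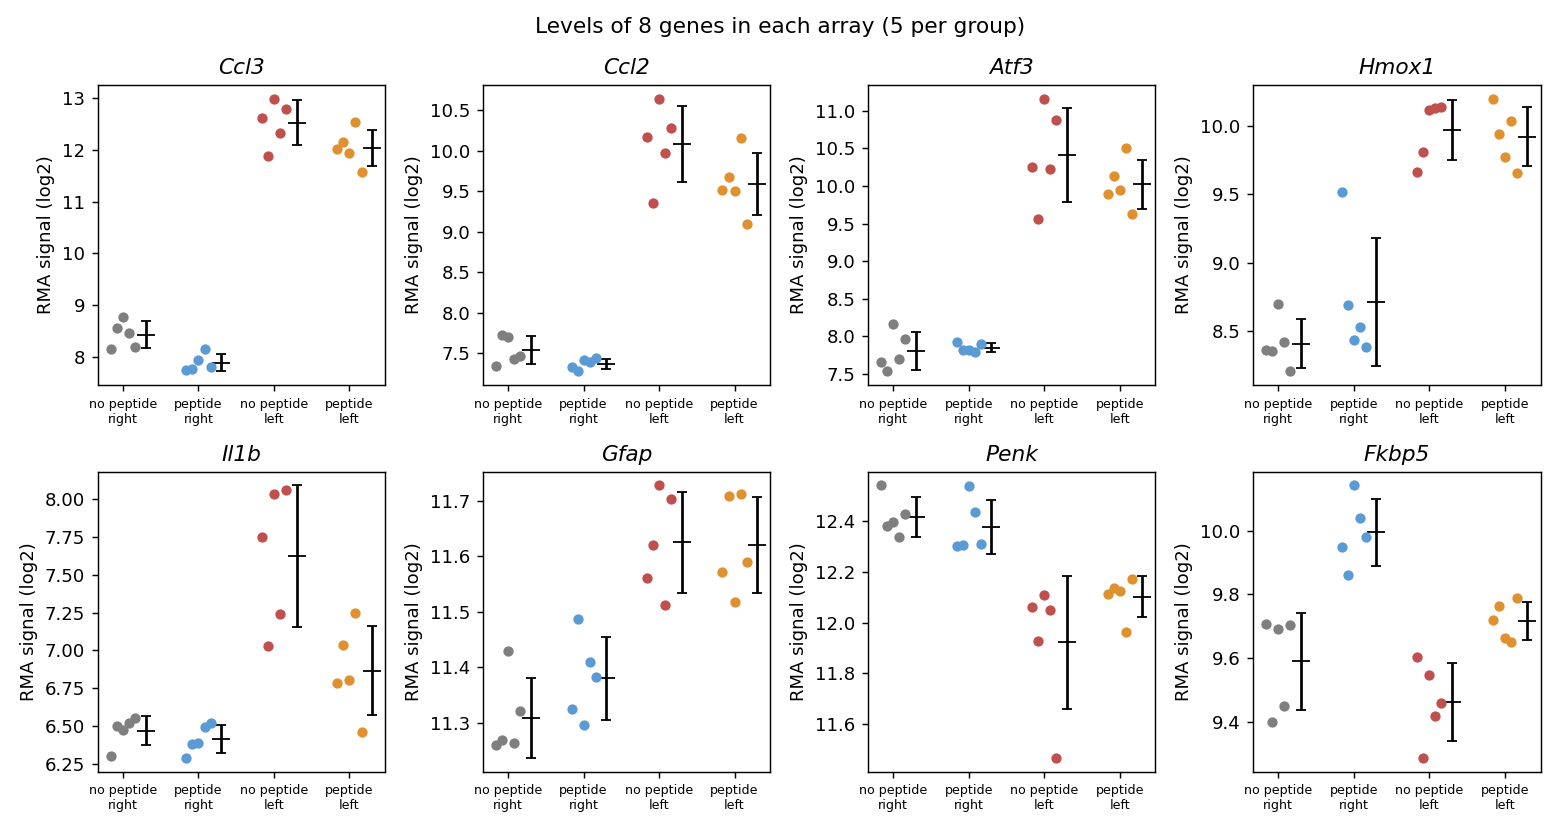
RMA signal (log2) of 8 genes in each array, 5 arrays per group, with the mean and SD beside the points. Ccl3 was 4.09 log2 units higher in the injured left hemisphere without peptide and 4.16 with it, whereas Gfap was 0.32 and 0.24 higher.

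The comparison of hemispheres in peptide-treated animals asks which part of the injury pattern was present with IDR1018. The same chemokine was at the top, with Ccl3 17.8-fold higher in the injured hemisphere (4.16 ± 0.14, SE, n = 5 per group, adjusted p = 5.4e-08). Ccl2 rose by 2.21 ± 0.14, Atf3 by 2.18 ± 0.12, Emp1 by 1.95 ± 0.08 and Lilrb4a, an inhibitory immune receptor, by 1.72 ± 0.13. Gadd45b, a stress-induced growth arrest gene, rose by 1.56 ± 0.10. The largest decreases were those of Mir421 (-0.90 ± 0.17), the organic anion transporter Slco1a4 of the blood-brain barrier (-0.81 ± 0.10), the Notch target Nrarp (-0.67 ± 0.03), the cortical neuron transcription factor Neurod6 (-0.66 ± 0.07) and the fibroblast growth factor receptor Fgfr3 (-0.62 ± 0.05).

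Most gene lists described without peptide had members past the test in the same direction with it. The ependymal and cilia list, which passed camera without peptide (10 of 10 positive values, median 0.11, 1 gene past the test and 0 over the list alone; adjusted p = 0.019, and adjusted p = 0.34 with an estimated correlation), had 5 positive and 5 negative values with it (median -0.01; 1 gene rose and 1 fell). Of reactive astrocyte genes 15 of 20 rose (17 higher and 1 lower adjusted over the list alone), of phagocytic and activated microglia genes 14 of 19 (15 over the list alone), of heat shock and unfolded protein response genes 10 of 15 (14 over the list alone), of TLR and NF-kB genes 12 of 18 (15 over the list alone) and of extracellular matrix genes 11 of 19 (11 over the list alone). These 5 lists also passed with an estimated correlation, each with adjusted p = 0.023, and no other list did. The p53 and apoptosis list, which passed that test without peptide, did not pass it with peptide. Cytokine and chemokine genes rose in 14 of 24 cases (15 adjusted over the list alone; adjusted p = 0.067 with an estimated correlation), with Tnf at 0.51 ± 0.08. Il1b rose by 0.45 ± 0.12; its adjusted p of 0.023 became 0.0594 without peptide left replicate 2, 0.0528 without peptide right replicate 1, 0.05 (just above the threshold) without peptide right replicate 2 and 0.062 with all 4 groups in the fit. In all 9 alternatives ended the call, with adjusted p up to 0.109, reached without both arrays of peptide replicate 2. Immediate early genes rose in 14 of 20 cases (15 higher and 2 lower adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). Homeostatic microglia genes fell in 7 of 13 cases and rose in 1 (10 lower and 1 higher adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), among them the purinergic receptors P2ry13 (-0.56 ± 0.07) and P2ry12 (-0.39 ± 0.07). Striatal projection neuron genes fell in 6 of 10 cases (8 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), with Drd2 at -0.34 ± 0.06 and Penk at -0.27 ± 0.06. On the panel, Hmox1 rose by 1.21 ± 0.19, Cd68 by 0.46 ± 0.06 and Gfap by 0.24 ± 0.05; Lcn2 (0.28 ± 0.18), Mbp (0.04 ± 0.08), Snap25 (-0.02 ± 0.03) and Il10 (0.01 ± 0.09) did not pass the test.

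With peptide 4184 probe sets differed between hemispheres, 2191 higher and 1993 lower in the injured left, and at 1.5-fold or more 132 and 10; after median centring 1975 were higher and 2280 lower. Of these, 1676 of the higher and 1361 of the lower probe sets were shared with the comparison without peptide, against 202 and 176 for independent sets, and 0 went in opposite directions. In both comparisons all left arrays come before all right arrays, so a step between them would be shared too. The overlap cannot separate that from a shared injury pattern. Across 19937 genes, which are not independent replicates, the left-right differences with and without peptide correlated at r = 0.89 with a slope of 0.80. The slope is that of a regression on the differences without peptide, whose own noise lowers it. This value alone therefore does not show a smaller response with peptide. Leaving out both arrays of an animal lowered the count to 2323 for peptide replicate 2, 2606 for replicate 4 and 2732 for replicate 3, and it was 2921 with the level of the control probe sets as a covariate. Of all 19937 genes, 1818 were higher and 1587 lower with peptide, the shares against which the member counts of the lists are to be read. Of 43 lists 21 passed camera and 28 passed fry, and 5 of 100 splits of the arrays put as many lists past camera, against 0 of 99 after the group means were removed.

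**Figure D2:**
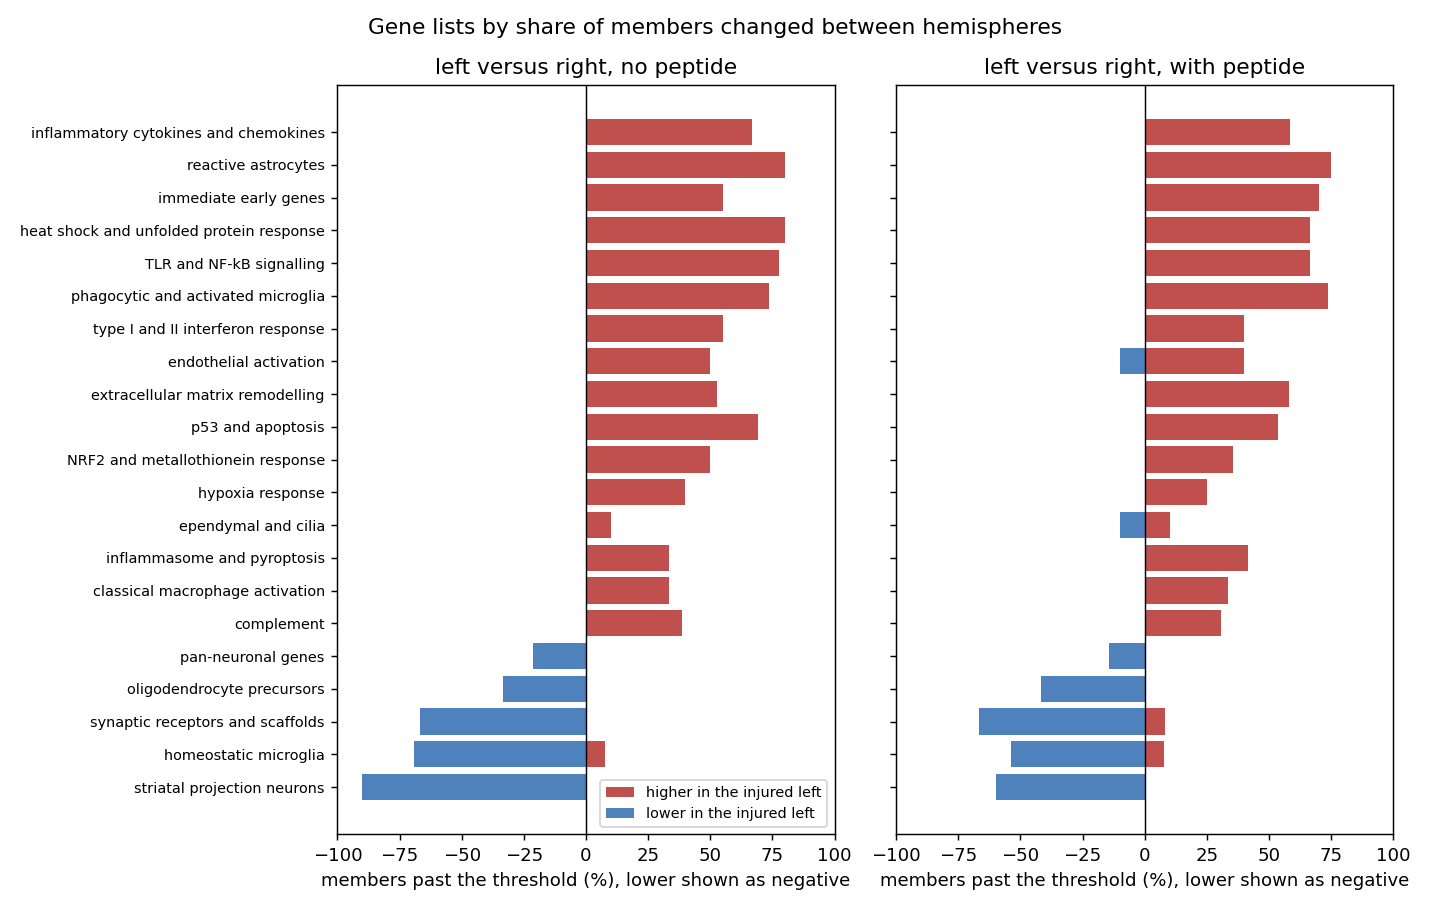
Share of the measured members of each gene list past the threshold, higher (red) or lower (blue, drawn as negative) in the injured left hemisphere, without peptide and with it, for the 21 lists past camera without peptide. Reactive astrocyte genes had 16 of 20 members higher without peptide and 15 of 20 with it.

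The comparison of peptide with no peptide in the injured hemisphere asks whether IDR1018 changed expression there. No gene passed the test. The largest differences on the panel were in cytokines: Il1b stood at 6.87 ± 0.30 (SD, n = 5) with peptide and 7.62 ± 0.47 without it, and Ccl2 at 9.59 ± 0.38 and 10.08 ± 0.47. The log2 fold changes were -0.76 ± 0.20 (SE) and -0.49 ± 0.22, and Il1a, another interleukin-1 gene, was at -0.86 ± 0.33. Kdr, the main VEGF receptor of endothelium, and Tnfsf10, the death ligand TRAIL, had the smallest p among lower genes, at -0.46 ± 0.07 and -0.48 ± 0.08 (adjusted p = 0.67 and 0.71). Among higher genes the smallest p belonged to C2cd6 (0.16 ± 0.03) and Mir221 (0.24 ± 0.05), both below the median of the control probe sets in all 20 arrays. Gfap (0.00 ± 0.05), Cd68 (0.05 ± 0.06), Hmox1 (-0.05 ± 0.12), Cxcl10 (-0.04 ± 0.17), Tnf (-0.19 ± 0.15), Lcn2 (0.39 ± 0.22), Il10 (0.05 ± 0.07), Mbp (-0.01 ± 0.07) and Snap25 (0.06 ± 0.03) did not pass the test either.

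Of cytokine and chemokine genes 20 of 24 had lower values with peptide, with a median of -0.16, and 0 passed, also when adjusted over the list alone. The list passed camera (adjusted p = 1.6e-08; adjusted p = 0.51 with an estimated correlation). Averaged per animal the list was 0.24 log2 units lower with peptide, a difference of -0.24 (two-sided exact permutation p = 0.0952, adjusted p = 0.597 over all list means). Of endothelium and blood-brain barrier genes 11 of 14 had lower values (median -0.10; adjusted p = 0.51 with an estimated correlation), with 0 past the test over all genes and 1 when adjusted over the list alone. Of choroid plexus genes 10 of 11 and of ependymal and cilia genes 10 of 10 had lower values (medians -0.10 and -0.07; adjusted p = 5.7e-05 and adjusted p = 0.00079 by camera, adjusted p = 0.51 for both with an estimated correlation), with 0 past the test. Averaged per animal these lists differed by -0.09 and -0.07 (exact permutation p = 0.0476 and 0.0635), and the inflammasome list by -0.11 (exact permutation p = 0.0397), all with adjusted p = 0.597. Of striatal projection neuron genes 9 of 10 had higher values (median 0.10; adjusted p = 0.58 with an estimated correlation), 0 of them past the test over all genes or adjusted over the list alone.

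By limma 0 of 28192 probe sets passed, with 1226 (4.35%) at an unadjusted p below 0.05, where chance gives 5%. Without peptide left replicate 5 the count was 1, Kdr at -0.53 (adjusted p = 0.0296). Camera put 12 lists past the threshold, but 0 passed with an estimated correlation, 0 passed fry, and 49 of 100 splits of these arrays gave as many. In a single simulated draw for this comparison the test with an estimated correlation missed a list shifted by 0.15 log2 units, which camera and fry found. Genes were drawn independently there, so the draw cannot tell how often each test finds such a shift in these arrays. The counts of 0 leave shifts of that size open.

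The same comparison in the uninjured hemisphere asks about peptide effects outside the injury. The genes with the smallest p among those higher with peptide were Osmr (0.33 ± 0.05, adjusted p = 0.27), the vasoconstrictor Edn1 (0.41 ± 0.06, adjusted p = 0.27) and Fkbp5, a glucocorticoid-induced regulator of the glucocorticoid receptor (0.40 ± 0.07, adjusted p = 0.64). Among lower genes they included the TLR-related receptor Cd180 (-0.25 ± 0.05), Ccl3 (-0.54 ± 0.12) and the microglial lectin Siglech (-0.21 ± 0.05), with adjusted p = 0.64, 0.64 and 0.75. Lcn2 stood at 10.43 ± 0.35 (SD, n = 5) with peptide and 9.69 ± 0.47 without it, a difference of 0.74 ± 0.22 (SE). Hmox1 (0.30 ± 0.19; 0.10 without peptide right replicate 1), Gfap (0.07 ± 0.05), Cd68 (-0.05 ± 0.05), Ccl2 (-0.17 ± 0.07), Tnf (0.12 ± 0.09), Il1b (-0.06 ± 0.06), Il10 (-0.01 ± 0.08), Mbp (-0.04 ± 0.08), Snap25 (-0.01 ± 0.03) and Cxcl10 (-0.01 ± 0.08) did not pass the test.

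All 11 measured glucocorticoid response genes had higher values with peptide in the uninjured hemisphere, and 10 of 11 did in the injured one. None passed over all genes; 9 passed when adjusted over the list alone in the right hemisphere and 1 in the left. The list mean per animal was 9.54 ± 0.05 (SD, n = 5) with peptide and 9.33 ± 0.10 without it on the right, a difference of 0.21 (two-sided exact permutation p = 0.00794, the smallest possible; adjusted p = 0.171 over all list means). The neutrophil list reached the same p and adjusted p there with a difference of 0.08, and the reactive astrocyte list, which shares Lcn2 with it, was 0.09 higher (exact permutation p = 0.0397, adjusted p = 0.427). Both passed camera on the right (adjusted p = 0.045 and adjusted p = 0.0048) but not with an estimated correlation (adjusted p = 0.51 for both), the neutrophil list also not with sex as a covariate or after cyclic loess, and they had differences of 0.01 on the left (exact permutation p = 0.817 and 0.905). On the left the glucocorticoid list was 0.13 higher (exact permutation p = 0.0317, adjusted p = 0.597). Part of that left difference came from no-peptide replicate 2, with a list mean of 9.21 against 9.36 or more in the other no-peptide animals. Camera gave adjusted p = 3.5e-16 on the right and adjusted p = 4.1e-05 on the left; with an estimated correlation these were adjusted p = 0.12 and adjusted p = 0.51. The list for cerebellum and other dissection regions, with 10 of 12 higher values on the right (median 0.07), passed camera there (adjusted p = 0.045) and likewise not with an estimated correlation (adjusted p = 0.51), with sex as a covariate or after cyclic loess. Homeostatic microglia genes were lower in 12 of 13 cases on the right (median -0.10; adjusted p = 0.51 with an estimated correlation), with 0 past the test over all genes and 1 adjusted over the list alone.

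By limma 1 probe set passed in the uninjured hemisphere, 10398039, which the annotation does not list. It is named after its values were seen. It stood at 7.24 ± 0.06 (SD, n = 5) with peptide and 6.69 ± 0.13 without it (adjusted p = 0.018), and was 0.17 ± 0.11 (SE) higher on the left. The unadjusted count was 1218 (4.32%). The call was lost (count 0) with all 4 groups in the fit, with the level of the control probe sets as a covariate, without any of the 5 peptide right arrays, and without no-peptide right replicate 1 or 5. Camera put 6 lists past the threshold (12 without peptide right replicate 3), 0 with an estimated correlation and 0 by fry, and 64 of 100 splits gave as many.

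**Figure D3:**
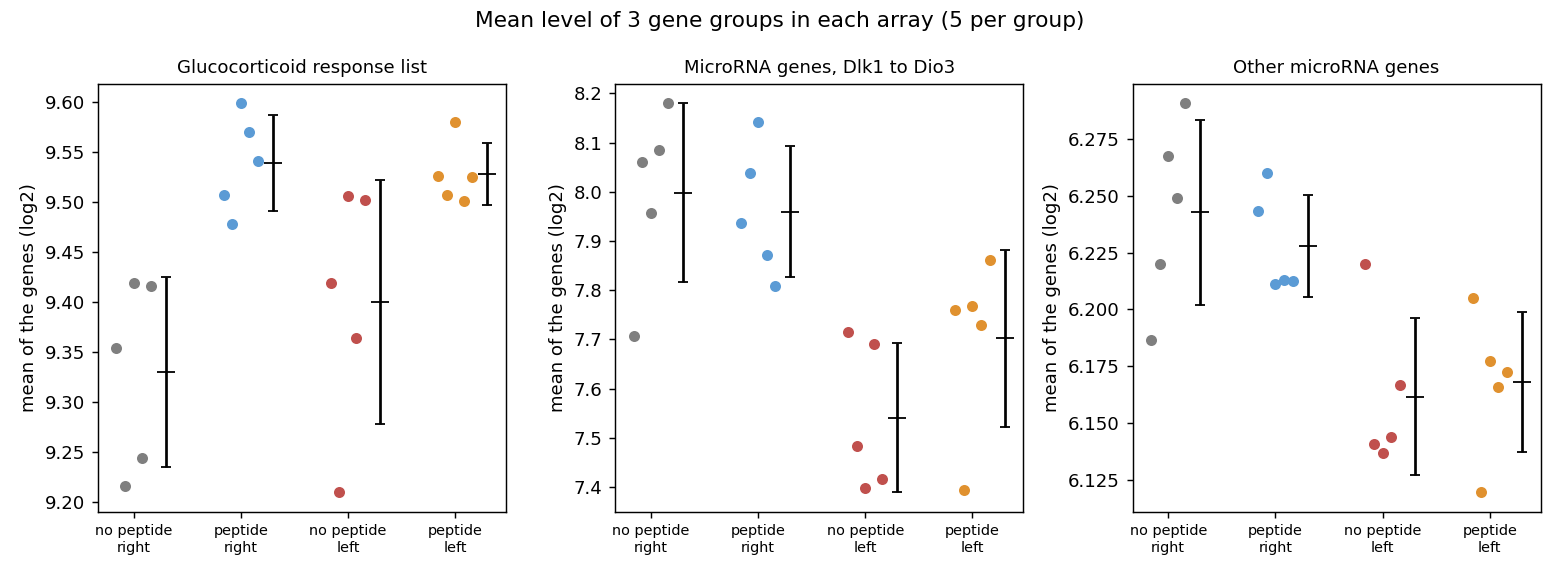
Mean log2 signal over the glucocorticoid response list, the microRNA genes between Dlk1 and Dio3, and all other microRNA genes, 1 point per array, with the mean and SD of each group of 5. The glucocorticoid list was 0.21 higher with peptide on the right and 0.13 higher on the left.

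The interaction asks whether the left-right difference itself changed with IDR1018. A negative term can come from lower values on the left or from higher values on the right. By itself it therefore does not show a smaller injury response. No gene passed the test. The left-right difference of Il1b with peptide minus that without was -0.70 ± 0.23 (SE, n = 5 per group). It was -0.45 ± 0.19 for the chemokine Ccl9, -0.47 ± 0.11 for Bcl2a1c, a member of the anti-apoptotic Bcl2a1 family, and -0.29 ± 0.10 for the metalloreductase Steap4, all with adjusted p = 1.00. Mir221 had the smallest p among positive differences (0.30 ± 0.07). Mir221 lay below the median of the control probe sets in all 20 arrays and Bcl2a1c in 19 of them. On the panel the differences were -0.33 ± 0.26 for Ccl2, -0.32 ± 0.18 for Tnf, -0.35 ± 0.24 for Hmox1 (-0.15 without peptide right replicate 1), -0.35 ± 0.34 for Lcn2, -0.08 ± 0.07 for Gfap, 0.09 ± 0.08 for Cd68, 0.07 ± 0.04 for Snap25, 0.03 ± 0.11 for Mbp, 0.06 ± 0.11 for Il10 and -0.03 ± 0.20 for Cxcl10.

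Of cytokine and chemokine genes 21 of 24 had a negative interaction term (median -0.16; adjusted p = 1.6e-06 by camera and adjusted p = 0.56 with an estimated correlation). Of striatal projection neuron genes 9 of 10 had a positive one (median 0.11; adjusted p = 0.56 with an estimated correlation). In both lists 0 members passed, over all genes or adjusted over the list alone. The interaction count by limma was 0, with 781 probe sets (2.77%) at an unadjusted p below 0.05. Camera put 14 lists past the threshold, and 3 without no-peptide left replicate 3, 4 without no-peptide left replicate 5, 7 without peptide left replicate 1, 7 without no-peptide right replicate 2, 8 without peptide right replicate 4, 9 without peptide right replicate 1 and 9 without no-peptide right replicate 4; 0 lists passed with an estimated correlation and 0 by fry, and 20 of 100 splits gave as many.

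The injury scores combine the injury genes into 1 value per animal. Over the 200 genes that rose most strongly, the left hemisphere was 0.66 ± 0.06 (SD, n = 5) log2 units higher with peptide and 0.73 ± 0.09 higher without it. The difference of -0.07 had a 95% interval from -0.18 to 0.04 and a two-sided exact permutation p of 0.159. With sex in the model and the treatment permuted within the sexes, an analysis added after the data were seen, it was -0.09 (exact permutation p = 0.05), which is at the threshold and not below it. Over the 200 genes that fell most strongly the scores were -0.33 ± 0.05 and -0.35 ± 0.04, with a difference of 0.01, an interval from -0.06 to 0.08 and exact permutation p = 0.635. Across genes, with no array shared between them, the peptide effect and the injury effect correlated at r = -0.13 (exact permutation p = 0.413 over 252 arrangements of the left arrays). Over these arrangements the split correlation ranged from -0.42 to 0.33. When arrays were shared the correlation was -0.38, against a mean of -0.20 in simulated groups with no peptide effect. Genes were drawn independently in that simulation, unlike in the arrays, so the distance between these values decides nothing.

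**Figure D4:**
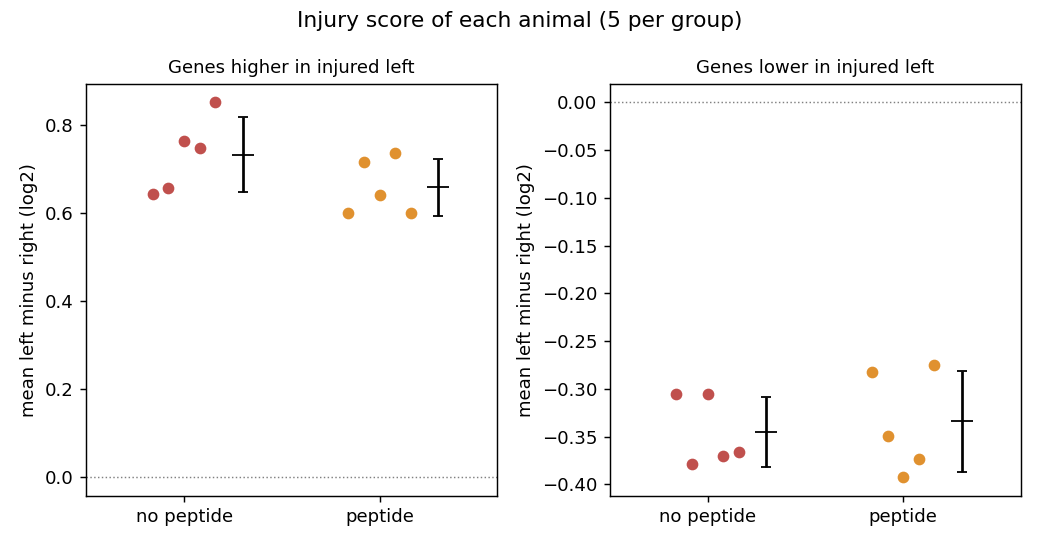
Injury score of each animal, the mean left minus right log2 difference over 200 genes higher and 200 genes lower in the injured hemisphere, with the mean and SD of 5 animals beside the points. The scores of higher genes averaged 0.66 with peptide and 0.73 without it.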

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

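The tests of sex and of one animal for the glucocorticoid list, and those for the crystallin genes, were chosen only after the results were seen; the tests of clock genes and of chance among the lists were written down after the pattern was seen but before their own values. In 292 sets of 5 arrays or animals a test for a sample far from the others found 20, where chance gives about 1 set in 20, or 14.6. The 20 include Cryaa and Crygd in both no-peptide groups and Cryba1 in the right one. All of these come from no-peptide replicate 5 and are on no fixed list. The count of 20 is therefore not read as more than chance gives, and the values below are listed as a description. In the no-peptide left group Ifit3 was 9.94 in replicate 5 against 9.41 or less in the others, Penk 11.47 in replicate 5, Meg3 12.50 in replicate 2 and Mir221 5.86 in replicate 3. In the no-peptide right group Ccl6 was 7.96 in replicate 1, Fosb 8.37 in replicate 3 and Slc6a13 10.16 in replicate 2. In the peptide left group Il1a was 6.72 in replicate 5 against 7.72 or more in the others, Hspb1 11.26 in replicate 4, Neurod6 9.70 in replicate 3, and Mir421 5.12 and Rian 9.36 in replicate 2. In the peptide right group Hmox1 was 9.52 in replicate 1 against 8.69 or less in the others, Cxcl10 6.96 in replicate 5 and Dlk1 9.31 in replicate 3.

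Of 13 crystallin genes, which encode abundant lens proteins, 12 had their highest value of all right arrays in the no-peptide animal 5, several by a wide margin and others, such as Cryba4, by little. Crygd was 8.99 in its right and 7.59 in its left hemisphere, against 5.85 and 5.36 or less in the other arrays of the same hemisphere. Cryaa was 9.30 and 8.40, and Cryba1 was 8.42 on the right. Against a fault of a single array, 9 of 13 crystallins had their highest value of all left arrays in the left array of this animal too, while any other left array held at most 1; against a response confined to the injured hemisphere, 12 of all 13 had a larger excess over the other arrays on the uninjured side, Crybb2 being the exception. Carried-over lens tissue stays open, because only 1 of 7 other lens genes was highest in that right array, against up to 3 in another, and a small share of lens RNA could raise the abundant crystallins alone.

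A glucocorticoid response list 0.168 log2 units higher with peptide over both hemispheres of each animal was the list difference with the smallest exact permutation p (0.00794), which is also the smallest possible. With sex of the animals in the model the difference was 0.168 (exact permutation p = 0.0200 within the sexes), and with any one animal left out it was at least 0.130. Clock genes of opposite phases (9 measured of one and 2 of the other), which a different time of day of collection can move apart, differed between the groups by 0.00213 with a 95% interval from -0.11 to 0.12. The values for sex and for omitted animals argue against sex and one animal as the whole source. Time of day stays undecided, because different times can give the same difference of phases. How far clock genes and this list move together was also not measured. Chance among the lists tested stays open, since in a share of 0.286 of the arrangements of the animals at least 1 list reached as large a statistic. Handling stress or the procedure of giving the peptide, which could act through the same hormone, was not tested. The sample titles name neither a route for the peptide nor a vehicle for the animals without it.

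The test of the left-right difference with against without peptide put 14 lists past camera, none with an estimated correlation. Their median interaction terms were -0.16 for cytokines and chemokines, -0.14 for immediate early genes, -0.13 for ependymal and cilia genes, -0.12 for endothelial activation, -0.10 for endothelium and blood-brain barrier, -0.0724 for reactive astrocytes, -0.0632 for TLR and NF-kB signalling, -0.0599 for extracellular matrix remodelling, -0.0590 for glucocorticoid response, -0.0550 for phagocytic and activated microglia, -0.0469 for p53 and apoptosis, -0.0435 for blood monocytes and macrophages, 0.0717 for oligodendrocyte precursors and 0.11 for striatal projection neurons. In means per animal, several of these differences lay more on the uninjured right side. With peptide the reactive astrocyte list differed by 0.01 on the left and 0.09 on the right. The TLR and NF-kB list differed by -0.03 and 0.05, and the p53 and apoptosis list by -0.02 and 0.05. Others lay mostly on the left, with -0.24 and -0.04 for cytokines and chemokines and -0.16 and -0.01 for immediate early genes.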

How the results depend on the processing

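The omission of whole animals, sex or the level of the control probe sets as a covariate, the permutation within the sexes, the restriction to probe sets of 1 gene, and list tests on other normalisations or with 1 array left out were chosen only after the data were seen. Counts between hemispheres moved by more than 1.5 times with a fold threshold and with 1 animal left out, which also leaves fewer arrays. At 1.5-fold or more they were 226 without peptide and 142 with it. Without both arrays of 1 animal they were 3325, 2788 and 2698 for no-peptide replicates 2, 4 and 5, and 2323, 2732 and 2606 for peptide replicates 2, 3 and 4. With the level of the control probe sets as a covariate the count without peptide was 2927, and with peptide it was 2921. With 1 array left out the range was 3681 to 4907 without peptide and 3126 to 3729 with it. The peptide count in the injured hemisphere ranged from 0 to 1 with 1 array left out, the 1 being Kdr without peptide left replicate 5. The peptide count of 1 in the uninjured hemisphere was 0 at 1.5-fold or more, with dim probe sets left out, with the level of the control probe sets as a covariate, with the replicate block (which has no basis here, since replicate numbers do not pair animals across treatments), with probe sets of 1 gene only, with all 4 groups in the fit and with specimen as a random block. It ranged from 0 to 1 with 1 array left out, and was 0 without any of the 5 peptide right arrays and without no-peptide right replicates 1 and 5. Leaving out dim probe sets or unnamed ones removes the probe set itself, which ends the call by construction where it is removed; otherwise the cause was not tested. The replicate block changed no other probe set count beyond 1.5 times; among the single genes followed through the alternatives it ended the calls of Mir411 without peptide and Gria3 with peptide and began that of Lcn2 without peptide, and among lists it ended that of complement without peptide. The interaction count was 0 in all alternatives.

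With an estimated correlation the lists past the threshold were 1 and 5 for the hemispheres without and with peptide, and 0 for both peptide comparisons and the interaction; fry gave 0 for the latter 3. With 1 array left out the counts ranged from 19 to 24 and from 18 to 24 for the hemispheres, from 8 to 18 for the peptide in the injured and from 5 to 12 in the uninjured hemisphere, where 12 came without peptide right replicate 3. For the interaction they ranged from 3 to 21, with 3 without no-peptide left replicate 3, and with 1 animal left out they were 22, 6 and 3 for no-peptide replicates 1, 3 and 5 and 5 and 9 for peptide replicates 1 and 3. The interaction of the immediate early gene list turned direction in its test without both arrays of no-peptide replicate 3, where the mean of its members was -0.02, and with 1 array left out the mean ranged from -0.25 to -0.0145. The cause was not tested. Of named genes called between hemispheres without peptide, 42 of 62 kept their call in all alternatives and 0 lost it with 1 array left out. With peptide these were 36 of 63 and 4. The fold threshold, which ends the call of any smaller change by construction, ended 17 of the calls without peptide and 26 with it. Under the other alternatives calls were lost for Fas, Mir411 and Mir539 without peptide, and for Gria3, Il1b, Mir379 and Usp18 with it. The difference in injury score of higher genes ranged from -0.10 to -0.04 with 1 animal left out, that of lower genes from -0.00394 to 0.0255, and with 1 array left out the split correlation ranged from -0.19 to -0.06, none past the test. With treatment permuted within the sexes the score difference of higher genes was -0.09 (exact permutation p = 0.05) and that of lower genes 0.01 (exact permutation p = 0.58). The deposited values hold no detection calls, so signal over background was not tested. The control probe sets, a mixed set with an upper quartile of 8.44 and so no measured background, had medians of 6.68 to 7.01 per array. Of 145 named genes, 24 lay below them in all 5 arrays of a group, so their folds involve dim values. Among them were Il1b and Il1a in both right groups, Mir421 in both left groups, and Mir379, Il10, C2cd6 and Mir221 in all 4.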

Other observations

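The tests in this part were chosen only after the results were seen. Genes for ribosomal proteins, which build the ribosome, were mostly higher in the injured hemisphere. Without peptide 24 of 57 rose and 0 fell, with a median log2 fold change of 0.11, and 53 of 57 had positive values. With peptide 6 rose and 0 fell, with a median of 0.09. Rpl12 had the largest increase, 0.76 ± 0.09 (SE, n = 5 per group) without peptide and 0.68 with it. After cyclic loess normalisation the medians were 0.13 and 0.10, so the direction did not depend on that scaling. Per animal the left-right difference of these genes went against that of the control probe sets (r = -0.90 over 10 animals); it was 0.11 as measured and 0.07 at equal control level (95% interval 0.04 to 0.10). Between peptide and no peptide the medians were -0.01 on the left and 0.03 on the right, with 0 genes past the test.

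MicroRNA genes of the imprinted domain between Dlk1 and Dio3 (neighbours in assembly GRCm38.p6) were lower in the injured hemisphere. Without peptide 30 of 40 fell and 39 of 40 had negative values, with a median of -0.46 (-0.44 after cyclic loess), whereas of 247 other microRNA genes 25 fell, with a median of -0.06. The long noncoding RNAs of the same domain, Meg3 and Rian, fell by 0.22 and 0.35 without peptide. With peptide they stood at -0.19 and -0.18, and neither passed the test. Dlk1 and Dio3 themselves did not pass in either comparison of hemispheres. Of the microRNA genes of the domain 13 of 40 fell with peptide, with a median of -0.27. The cluster mean was lower on the left in 8 of 10 animals (exact sign-flip permutation p = 0.00781). Its left-right difference was -0.46 ± 0.29 (SD, n = 5) without peptide and -0.26 ± 0.26 with it (exact permutation p = 0.310), so a peptide effect on it is not shown. The median of the control probe sets moved with it, being lower on the left in 7 of 10 animals.

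As the source of the decrease in these microRNA genes, a fall of all microRNA probe sets alike is argued against, because the lowest median among 10000 random sets of other microRNA genes was -0.12. These sets were matched to the cluster by bins of level, but the lowest bin took in all dimmer genes. The match is therefore partial, with median levels of 6.24 for the other microRNA genes and 7.62 for the cluster. A uniform loss of neurons is argued against too, since the most reduced pan-neuronal gene was at -0.39 and the median of that list at -0.08; a loss of particular neurons that express the domain more strongly is not excluded, and striatal projection neuron genes had a median of -0.39. Array order cannot be told apart from hemisphere: within hemispheres the slope over 10 arrays was 0.0761 (95% interval -0.20 to 0.35), which may speak against a steady drift but leaves a step between the left and right arrays open. The level of the control probe sets also accompanied the decrease (r = 0.93 between the left-right differences of 10 animals): at equal control level the cluster difference was -0.16 (95% interval -0.27 to -0.06) in place of -0.36, which argues against this array-level shift as the whole source but leaves open that it made up the larger part. A lower activity of the domain in injured tissue is thus a hypothesis that these arrays cannot settle.

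Other splits of the arrays into 5 and 5, 100 for each comparison with the real one included, were counted for probe sets and lists. For the hemispheres only the real split, 1 of 100, gave as many probe sets. The counts were 5088 without peptide against at most 4 in another split, and 4184 with peptide against at most 1. Among the 16 splits that part all pairs of arrays of an animal the highest other counts were 4 and 1 as well. These 16 splits keep each animal in both groups and differ from the real one in mixing the hemispheres. Mixing adds the real difference to the residual variance, which keeps the other counts low, and with 16 splits the smallest possible share is 1 of 16. The splits therefore do not exclude chance by themselves, and the hemisphere counts rest on the adjusted p of limma. In the uninjured hemisphere 2 of 100 splits gave 1 or more, the highest other being 2, which adds little to the adjusted p of that single probe set and makes no allowance for the 5 comparisons, so chance is not taken as excluded there. For the peptide in the injured hemisphere and for the interaction the real count was 0, which 100 of 100 splits reach by construction, so these splits decide nothing. The highest other counts there were 7, in a split that parted the sexes completely, and 1.

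For lists past camera 29 of 100 splits gave 21 or more for the hemispheres without peptide (highest other 28) and 5 of 100 with peptide (25). Of the 16 splits that part all pairs of an animal, 4 gave as many without peptide (highest other 27) and 3 with peptide (23). All of these but the real split mix unequal numbers of left and right arrays and so carry part of the real difference, which leaves them unable to decide. After the group means were removed 11 of 99 splits gave as many without peptide (highest 29) and 0 of 99 with peptide (highest 20). By these splits chance is not excluded without peptide, whereas with peptide none reached the real 21, the closest by 1 list. Chance is not excluded for the peptide in the injured hemisphere, where 49 of 100 splits gave 12 or more (highest other 30), in the uninjured one, where 64 of 100 gave 6 or more (13), or for the interaction, where 20 of 100 gave 14 or more (25). Members of a list varied together between arrays of a group: the median of the estimated correlation over the 43 lists was between 0.175 and 0.286 in the 5 comparisons, against the preset 0.01 of camera.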
